A study of Homo sapiens with 10 samples.

How the data were processed

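MicroRNA (miRNA) profiles were measured on 10 one-colour (Cy3) Agilent miRNA arrays, each hybridised with total RNA of one sample of MCF10A.B2 cells. By the sample labels, 5 samples were control cells transduced with an empty retroviral vector and 5 were Cas/ErbB2 cells transduced with p130Cas fused to GFP. The titles call them biological replicates 1 to 5 of each group, without saying what was separate between replicates, so p-values measure the spread between these samples.

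The scanner images were quantified with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited spot values are intensities on a linear scale: a mean signal, a local background and a processed signal from which background had been subtracted, with no normalization between arrays, per the file headers. The same files hold a total gene signal per miRNA, set to 0.1 where a miRNA was not detected, per the file headers. The series also has a value table made by the authors, with intensity values for 175 miRNAs and 58 empty cells. All 58 empty cells belong to miRNAs that the scanner files give as not detected on that array. Set against the total gene signal of the same array, the authors' deposited values followed it apart from one factor per array, with a lowest correlation of 1.00 across miRNAs, once 2 cells of Cas/ErbB2 replicate 2, over 4-fold away and not detected per the scanner file, were left out. Direction and scale are therefore those of the scanner files, and the way the factor was chosen is not given in the sources used here. The medians of the 10 columns lay between 5.14 and 5.57 (log2).

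Each array held 15739 spots, of which 715 were control spots and 15024 belonged to 2689 probes for 939 miRNAs, 851 human and 88 viral. Control spots and spots marked as outliers by the scanner software were left out, and the processed signal was averaged over the spots of each probe. A probe was taken as above background on an array where at least 0.5 of its kept spots were marked well above background. As 227 probes met this on all 10 arrays, each array was divided by its 75th percentile over those 227 probes. A floor was then set at the median over arrays of the lowest scaled signal among probes above background, which was 0.0306 (−5.03 on the log2 scale), and log2 was taken. A miRNA's value was the mean over its probes above background on all arrays of at least 1 group. This kept 261 probes and 143 miRNAs. The rule uses the group labels, so a miRNA could enter only through the group in which it was brighter. For 10 of the 143, the probes differed in the sign of the change. Values at the floor have no order, and the size of a change measured against them depends on the floor.

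The 143 miRNAs were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Cas/ErbB2 minus control, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a miRNA was above background on no array of a group, a bound is given: the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal above background and the miRNA's own value. Errors of fold changes are standard errors of the fit. Before the data were examined, 20 lists of miRNAs (families, genomic clusters, reported functions, markers of other cell types and signals of doubtful origin) were written down, along with the tests, the alternatives and the rule for naming miRNAs. Of these, 17 had at least 2 tested members and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Named were the 12 largest increases and the 12 largest decreases past the threshold, or, with fewer than 5 in a direction, the 5 with the smallest p. From each list up to 4 tested members with the smallest p were named too. Other miRNAs are said to have been chosen after their values were seen. The number of detected miRNAs per array was compared with an exact two-sided permutation test over all 252 assignments of the arrays.

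The arrays lay on 2 slides, scanned in 2 sessions. Slide 1 held 2 control and 3 Cas/ErbB2 arrays, and slide 2 held 3 control and 2 Cas/ErbB2 arrays. Fits with slide as a block and values within each slide are given. On both slides every control array lay in the first row and every Cas/ErbB2 array in the second, so row and group cannot be told apart. No 2 arrays were near-copies: the SD of the log2 differences between arrays of a group was 0.23 to 0.53.

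The groups share replicate numbers. The deviations of same-numbered arrays from their group means correlated, across miRNAs, at 0.83, 0.45, 0.45, 0.70 and 0.13 for numbers 1 to 5. All lie above 0.1, so the numbers were taken to pair the samples. For numbers 2, 3 and 5, though, the control array correlated more with a Cas/ErbB2 array of another number, so the pairing is uncertain. Numbers 1 to 4 share a slide within the pair and number 5 does not, so part of this pairing may come from the slides. The fit with the number as a block is given beside a result where it changes it.

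The fitting and list scripts were tested on simulated data: 100 datasets of 143 miRNAs with the real means and spreads, 20 miRNAs changed by 0.5 and 20 by 1 (log2). The fit recovered 72.0% of the former and 93.7% of the latter, and 3.74% of its calls were false. A list shifted by 0.5, the let-7 family with 9 tested members, was called in all simulated datasets. The simulated miRNAs varied independently, without slides, pairs or correlation within lists. More of them were changed than the 11 called on the real arrays, and Benjamini-Hochberg adjustment recovers each change more easily where more are present. These rates therefore need not hold for the real arrays or for smaller lists.

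Alternatives covered other scalings (the 75th percentile over all probes, the median, quantile normalization, none), normexp background correction with an offset of 50, a lower floor, other probe summaries, other filters on dim probes, replicate number or slide as a block, trended and robust moderation, array weights, the authors' values, and leaving out each array. Chromosomes are those of the probe mappings in the scanner files. The header names a genome build that those mappings do not fully follow, so no base positions are given. Neighbouring miRNA genes were found by gene symbol in a RefSeq table of assembly GRCh38.p14. The arrays measure miRNAs only, so p130Cas and ErbB2 transcripts were not measured and the overexpression was not checked here. Figures were drawn with matplotlib 3.10.9.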

Results

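MCF10A.B2 is a derivative of MCF-10A, a human mammary epithelial line that is not tumorigenic by itself, although the labels list it under breast cancer. In both groups the ErbB2 receptor tyrosine kinase was activated, and the Cas/ErbB2 group also overexpressed p130Cas, an adaptor protein in integrin and growth factor signalling. The comparison asked which miRNAs differ when p130Cas is added to active ErbB2, a combination studied for invasion. The series text speaks of acini and the sample labels of cells, and the files do not settle which was used. Each group had 5 arrays. The arrays detected 133 to 169 miRNAs each, on average 156.8 ± 8.53 (SD, n = 5) in control and 155.8 ± 15.2 (SD, n = 5) in Cas/ErbB2 cells. These numbers did not differ beyond the spread between arrays (exact two-sided permutation p = 0.93, n = 5 per group, smallest possible p = 0.0079). The 75th percentiles used for scaling lay between 246.2 and 420.9 intensity units, and no miRNA spot was saturated. The number of arrays limits the precision.

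Of the 143 tested miRNAs, 11 changed in Cas/ErbB2 cells, 4 higher and 7 lower. All 11 had the same direction on both slides and in all 5 numbered pairs, and in 10 of them the groups did not overlap, as in 8.39% of all tested miRNAs, where chance gives 0.79%. The 11 were called on these same arrays, so the shared directions and the lack of overlap were largely built in. Some miRNAs that did not pass, such as miR-98 and miR-221, also kept their direction in all 5 pairs. None changed at least 2-fold with limma, and none did so at an unadjusted p under 0.05, while 30 miRNAs of any size were under that value. The count of changes of at least 2-fold depends on the floor and the scaling, as given below. With other scalings 2 (percentile over all probes), 8 (median), 4 (none) and 13 (quantile normalization, 6 higher and 7 lower) changed. With the replicate number as a block, 26 changed, 7 higher and 19 lower, and with slide as a block 18, 7 higher and 11 lower. Both fits kept the 11.

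Higher in Cas/ErbB2 cells were miR-222, miR-424, miR-200b and miR-100. miR-222 (chromosome X), which is processed from one primary transcript with miR-221, rose by 0.92 ± 0.20 (SE, log2), or 1.89-fold, from −1.48 ± 0.42 to −0.56 ± 0.30 (SD, n = 5, adjusted p = 0.015). The groups overlapped, and 1 of the 2 miR-222 probes was above background. miR-222 missed the threshold with no filter, where the probe below background enters the mean (0.40 ± 0.17, adjusted p = 0.38), and without both arrays numbered 5 (0.76 ± 0.23, adjusted p = 0.090). It also missed with normexp without its offset (0.84 ± 0.20, adjusted p = 0.051) and on slide 2 alone (0.66 ± 0.29, adjusted p = 0.35). miR-424 (chromosome X), a member of the miR-15 family by its seed, rose by 0.78 ± 0.16, or 1.72-fold (adjusted p = 0.012), but had 0.16 ± 0.11 with normexp background correction (adjusted p = 0.41), 0.46 ± 0.18 with normexp without its offset and 0.24 ± 0.10 with the offset alone. miR-424 also missed the threshold with the percentile over all probes (adjusted p = 0.098) and with no filter (adjusted p = 0.20). miR-200b (chromosome 1), known for repressing the epithelial-mesenchymal regulators ZEB1 and ZEB2, rose by 0.58 ± 0.12, or 1.49-fold (adjusted p = 0.012). Its level lay near background, with 3 of 5 control arrays and 5 of 5 Cas/ErbB2 arrays above it. The rise of miR-200b all but vanished with normexp background correction (−0.04 ± 0.12), with normexp without its offset (0.08 ± 0.21) and with the offset alone (0.03 ± 0.09). miR-200b also missed the threshold with the percentile over all probes (0.56 ± 0.26, adjusted p = 0.69) and with no filter (0.29 ± 0.06, adjusted p = 0.15). miR-100 (chromosome 11) rose by 0.32 ± 0.07, or 1.25-fold, from −0.27 ± 0.06 to 0.06 ± 0.08 (SD, n = 5, adjusted p = 0.015). It missed the threshold in 7 of 26 planned settings: the percentile over all probes (adjusted p = 0.97), no scaling (0.32), normexp (0.067), the total gene signal (0.052), and without control replicate 1, 2 or 5 (adjusted p = 0.055, 0.059 and 0.066, range over its alternatives 0.0057 to 0.97). The fifth increase by p, miR-221*, the passenger strand of miR-221, did not pass (0.29 ± 0.10, adjusted p = 0.10). It passed in 5 of 26 planned settings: the replicate number as a block (adjusted p = 0.038), slide as a block (0.024), quantile normalization (0.0050), the brightest probe (0.049) and the authors' values (0.0057). Over all planned settings its change lay between −0.087 and 0.46.

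Lower in Cas/ErbB2 cells were miR-455-3p, miR-378, miR-1290, miR-513b, miR-23b, miR-149 and miR-181a*. miR-455-3p (chromosome 9) changed by −0.93 ± 0.11 (SE, log2; adjusted p = 0.00061), from −4.06 ± 0.22 to −4.98 ± 0.11 (SD, n = 5). It was above background on all 5 control arrays and on 2 Cas/ErbB2 arrays, and 4 of the 5 Cas/ErbB2 values lay at the floor, which therefore sets the size of the change. The floor also narrows the Cas/ErbB2 spread that enters its p. Over the alternatives miR-455-3p had −1.82 to −0.25, the latter with normexp (adjusted p = 0.34). miR-378 (chromosome 5), whose gene lies within that of the transcriptional coactivator PPARGC1B, changed by −0.74 ± 0.14, a 1.67-fold decrease (adjusted p = 0.0069). miR-513b (chromosome X) changed by −0.59 ± 0.10, a 1.51-fold decrease (adjusted p = 0.0059). Its Cas/ErbB2 values (−4.77 ± 0.11, SD, n = 5) lay near the floor. miR-23b (chromosome 9), which is clustered with miR-27b, was the brightest of these and changed by −0.53 ± 0.10, a 1.44-fold decrease, from 1.26 ± 0.11 to 0.73 ± 0.16 (SD, n = 5, adjusted p = 0.0069). miR-181a* (chromosome 1), the passenger strand of miR-181a, changed by −0.43 ± 0.10 (adjusted p = 0.015), and missed the threshold in 7 of 26 planned settings, among them the median as scale (adjusted p = 0.12), the total gene signal (0.093) and the authors' values (0.059). Of these settings miR-378 missed it in 4, miR-513b in 3 and miR-23b in 2.

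miR-149 (chromosome 2) was above background on all 5 control arrays and on no Cas/ErbB2 array, so it was at least 1.30-fold lower there (adjusted p = 0.0097 in the fit). All its Cas/ErbB2 values lay at the floor (SD 0), so this p measures no spread between the samples of that group. miR-149 missed the threshold in 4 of 25 planned settings: the percentile over all probes (adjusted p = 0.69), the median as scale (0.082), no scaling (0.28) and normexp (0.41). miR-1290 (chromosome 1), one of the signals that may come from other RNAs, changed by −0.65 ± 0.17 (adjusted p = 0.035). It missed the threshold in 12 of 26 planned settings, the most of the 11, among them the median as scale (adjusted p = 0.082), quantile normalization (0.21), the total gene signal (0.093) and the authors' values (0.15). The 12 include the fits without control replicate 1, 2 or 4 or Cas/ErbB2 replicate 1 (adjusted p = 0.091, 0.099, 0.060 and 0.064, range over its alternatives 0.0051 to 0.50). miR-455-3p, miR-378, miR-149 and miR-1290 rested on 1 probe each, like miR-222 and miR-200b, and the other 5 on 2 probes that moved alike.

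**Figure D1:**
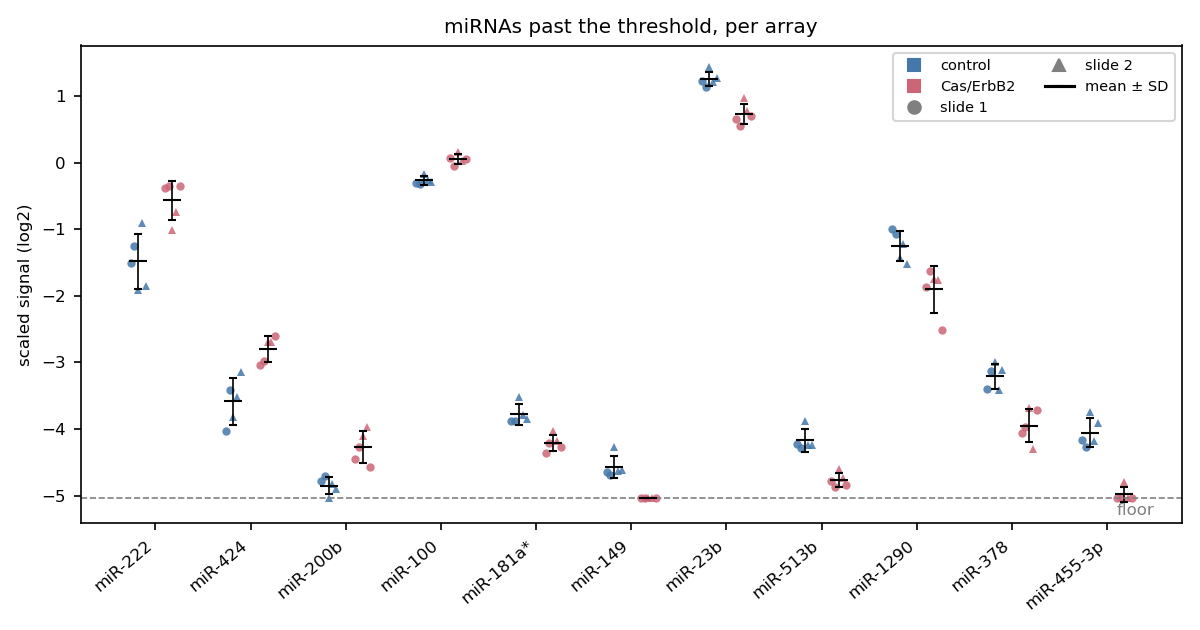
Scaled signal (log2) of the 11 changed miRNAs on each array, ordered by log2 fold change. Circles are arrays of slide 1 and triangles of slide 2, black marks show the mean ± SD (n = 5), and the dashed line is the floor at −5.03. All Cas/ErbB2 arrays lie at the floor for miR-149, and the groups overlap for miR-222.

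The changed miRNAs, which were called on the arrays of both slides together, had the same direction on each slide. On slides 1 and 2 the log2 change was 1.02 and 0.68 for miR-222, 0.85 and 0.80 for miR-424, and 0.34 and 0.33 for miR-100. For miR-200b it was 0.31 and 0.88. The miRNAs that were lower changed on slides 1 and 2 by −0.81 and −0.97 (miR-455-3p), −0.65 and −0.82 (miR-378), −0.97 and −0.36 (miR-1290), −0.58 and −0.55 (miR-513b), and −0.55 and −0.43 (miR-23b). For miR-181a* the values were −0.40 and −0.39, and miR-149 was lower on both slides, without a size because its Cas/ErbB2 values lie at the floor. Between the slides 35 miRNAs differed with group as a block, none of them among the 11. The median change of all tested miRNAs was −0.11, and 0.06 without scaling. Relative to the former the 4 miRNAs that rose stood 0.43 to 1.03 higher, and the 7 that fell stood at −0.32 to −0.82. With no scaling, 3 were called higher and 1 lower, with the median as scale 4 and 4, and with the percentile over all probes 1 and 1.

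Of the 17 tested lists, 2 changed as groups (camera, preset correlation), both upward. Neither passed with an estimated correlation (adjusted p = 0.15 for the miR-99 and miR-125 clusters and adjusted p = 0.17 for the miR-200 family), and both missed with the percentile over all probes, quantile normalization or no scaling (adjusted p = 0.054 to 0.069). In the miR-99 and miR-125 clusters, which lie on several chromosomes beside let-7 genes, 1 of 5 tested members rose over all miRNAs tested and 2 changed when adjusted over the list alone. The list's median change was 0.26 (camera adjusted p = 0.015). Beside miR-100, miR-125b had 0.37 ± 0.12 (adjusted p = 0.11), miR-99a 0.26 ± 0.12 (adjusted p = 0.25) and miR-99b −0.07 ± 0.18 (adjusted p = 0.85). miR-99b was above 0 with the median as scale and without scaling. With the replicate block miR-125b (adjusted p = 0.0099) and miR-99a (adjusted p = 0.047) passed too. Of 26 planned settings, miR-125b passed in 5 and miR-99a in 3. In the miR-200 family, 1 of 3 tested members rose, and 1 changed when adjusted over the list alone. The list's median was 0.16 (camera adjusted p = 0.042). Beside miR-200b, miR-141 had 0.16 ± 0.17 and miR-200c 0.07 ± 0.08 (adjusted p = 0.62 and 0.64). Of 100 splits of the arrays, 31 gave 2 or more lists. With the replicate block the miR-99 and miR-125 clusters had adjusted p = 0.012 and the miR-200 family adjusted p = 0.079. With slide as a block they had adjusted p = 0.017 and adjusted p = 0.057. Fits on slides 1 and 2 alone, with probes and scaling set anew, gave the clusters medians of 0.18 (6 tested members) and 0.24 (5 tested members). The family had 0.27 and 0.12 (3 tested members each).

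The miR-23 clusters and the miR-221 cluster missed the threshold (camera adjusted p = 0.061 and 0.070) but passed with fry, which asks whether a list moves one way on balance and gave adjusted p = 0.020 for both. With the replicate block fry gave 0.060 for the miR-221 cluster, which no longer passed, and 0.027 for the miR-23 clusters. For the miR-200 family and the miR-99 and miR-125 clusters fry gave 0.020 and 0.021. These fry values depend on the scaling. With the percentile over all probes (0.95 each) and with no scaling (0.36 to 0.84) none of the 4 lists passed, and the miR-23 clusters missed with the median (0.12) and quantile normalization (0.070) too, the miR-99 and miR-125 clusters with the median (0.060). Of the 5 tested members of the miR-23 clusters, 1 fell over all miRNAs tested and 2 changed when adjusted over the list alone. All were below 0, with a median of −0.27, except that miR-23a and miR-24 were above 0 without scaling. miR-27b, which lies next to miR-23b, had −0.49 ± 0.14 (adjusted p = 0.059, and 0.0088 with the replicate block). On chromosome 19, miR-27a had −0.27 ± 0.14 (adjusted p = 0.34, and 0.050 with the replicate block, just past the threshold) and miR-23a −0.16 ± 0.08 (adjusted p = 0.27). Of the 3 tested members of the miR-221 cluster, 1 rose, and 2 changed when adjusted over the list alone. miR-221 had −0.17 ± 0.09 (adjusted p = 0.31), against 0.92 for miR-222 from the same transcript.

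Among miRNAs reported to promote invasion, 1 of 7 tested members rose (miR-222), and 2 changed when adjusted over the list alone. The list had a median of 0.00 and a mean of 0.16 (camera adjusted p = 0.15), and fry's mixed test, which counts changes in either direction, passed (adjusted p = 0.0096) but missed with the percentile over all probes (1.00) and no scaling (0.99). miR-210, induced by hypoxia, had 0.35 ± 0.21 (adjusted p = 0.42). Of the 5 tested members reported to restrain invasion, none passed in either adjustment (median −0.07, camera adjusted p = 0.69). miR-31 had 0.16 ± 0.11, miR-193b 0.06 ± 0.09 and miR-31* −0.12 ± 0.12. miR-205 had −0.16 ± 0.15, and like miR-31* it was above 0 without scaling. Of the 4 reported to target ErbB receptors, none passed over all tested and 1 did when adjusted over the list alone (miR-125b). That list had a median of −0.07 (camera adjusted p = 0.69), with miR-331-3p at −0.25 ± 0.15 and miR-125a-5p at 0.02 ± 0.14.

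The miR-15 family was split. Of its 4 tested members miR-424 rose, and 3 changed when adjusted over the list alone, while miR-15a had −0.32 ± 0.12, miR-16 −0.29 ± 0.12 and miR-15b −0.15 ± 0.12. With the replicate block miR-15a and miR-16 passed as lower (adjusted p = 0.040 and 0.048). miR-15b was above 0 without scaling. The family's median was −0.22, but its mean was 0.01 and the test's direction upward (camera adjusted p = 0.97).

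No member passed over all miRNAs or over the list alone in the let-7 family (9 tested, median −0.10, camera adjusted p = 0.69), the miR-17 cluster and paralogs (9, −0.03, 0.69), the miR-183 cluster (3, −0.02, 0.69), the miR-29 family (3, 0.11, 0.16), the miR-30 family (6, −0.21, 0.69) or the miR-34 family (2, −0.23, 0.69). Members with the smallest p were miR-98 (−0.25 ± 0.09), miR-25 (−0.13 ± 0.12), miR-183 (−0.02 ± 0.07), miR-29b (0.25 ± 0.17), miR-30e* (−0.38 ± 0.17) and miR-34b* (−0.33 ± 0.14). With the replicate block miR-30e* (adjusted p = 0.042) and miR-34b* (adjusted p = 0.038) passed as lower, and with slide as a block miR-30c did (adjusted p = 0.0076). The sign of miR-25 flips without scaling, and that of miR-183 under each of the 4 other scalings. Among signals counted as fragments of other RNAs, 1 of 8 tested members fell (miR-1290), also when adjusted over the list alone (median −0.28, camera adjusted p = 0.48). miR-1308 had −0.34 ± 0.12 (adjusted p = 0.15, and 0.020 with the replicate block) and miR-1274b −0.39 ± 0.26 (adjusted p = 0.48). No GC-rich array signal (9 tested, median −0.12, camera adjusted p = 0.86) and neither of the 2 tested viral probes' miRNAs (median −0.20, camera adjusted p = 0.99) passed. camera compares a list with the other miRNAs, so its direction can be upward for a list with a median below 0. This was so for the miR-17 and miR-183 clusters and for the lists reported to restrain invasion or target ErbB receptors. For viral miRNAs it was upward too, although their median lay below the −0.11 of all tested miRNAs. At camera adjusted p = 0.99 that direction carries no information, and with the replicate block it was downward.

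Of markers of other cell types, none of the 9 stromal miRNAs was above background on any array. Of 11 blood cell miRNAs 1 was tested, miR-150* (−0.11 ± 0.23, adjusted p = 0.81), and of 56 from the chromosome 14q32 cluster 1 was tested, miR-494 (0.10 ± 0.58, adjusted p = 0.94). These were not tested as lists. Within slides 1 and 2 miR-494 had −0.17 and −0.36, so its sign in the fit without a block is opposite to that on each slide.

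**Figure D2:**
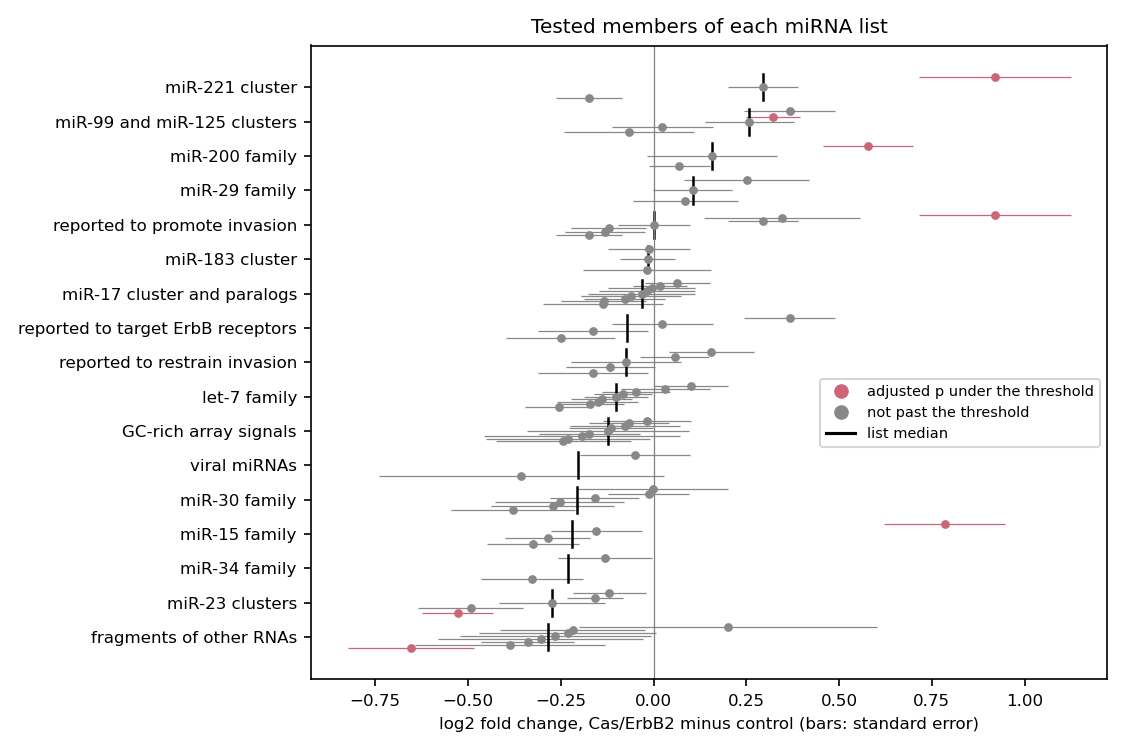
Log2 fold change (Cas/ErbB2 minus control) of each tested member of the 17 lists, with its standard error as a bar. Black lines are list medians, from −0.28 for fragments of other RNAs to 0.29 for the miR-221 cluster, and red points are members past the threshold over all 143 miRNAs.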

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

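The tests of one array, of cross-hybridization and of the array row, and the splits counted over all changed miRNAs with and without slide as a block, were chosen after the results were seen, as were the settings that separate normexp from its offset. Sets of 5 values were searched for an array far from the others of its group, and 7 of 142 sets held one, where chance gives about 7.10. The gap to the nearest array, as a share of the whole range, was 0.86 for miR-513b, 0.81 for miR-149 and 0.73 for miR-181a* in control cells, each time with control replicate 3 highest. In Cas/ErbB2 cells it was 1.00 for miR-455-3p, where replicate 3 lay above others at the floor. Cas/ErbB2 replicate 5 was lowest for miR-1290 (0.72) and miR-125a-5p (0.78) and highest for miR-1246 (0.83), with 1.72 against −0.29 or less on the other 4 arrays. It had the lowest array weight, 0.27, and without it 16 miRNAs changed.

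Of 100 splits of the arrays drawn from 126, 2 gave at least the 11 changed miRNAs, the real one and the one that follows the slides, which gave 36 and so points to a structure of the samples by slide. The highest of the others gave 7. With slide as a block the real split gave 18 and the highest of the others 15, so that 1 of 99 splits was as large. Both shares are under 0.05, but among splits that ignore the replicate pairs. Among the 16 splits that part all 5 numbered pairs, 1 gave 11 and the others 0 (with the number as a block 26 and 0), and 16 splits are too few for a share under 0.05. For miRNAs changed at least 2-fold the real count is 0, which all 100 splits reach whatever the data (the highest gave 3), so nothing was tested there. For lists, 31 of the 100 gave at least the real 2, the highest 4, so chance is not excluded for the number of lists.

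miR-222 rose while miR-221, from the same primary transcript, had −0.17. The difference between the changes was 1.09 ± 0.25 (log2, SE; exact two-sided permutation p = 0.0079, n = 5 per group, the smallest possible) and at least 0.98 without any one array, which argues against a single array as the cause. A fault of the one bright miR-222 probe stays open: the other probe, below background, differed by 0.0097 ± 0.0091 in scaled signal (SE; exact permutation p = 0.33, n = 5 per group). The array row also stays open, here and for all changes below, because it gives the group of 10 of the 10 arrays. A change in the processing or stability of the 2 miRNAs in Cas/ErbB2 cells may also produce this and was not tested.

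miR-23b and its neighbour miR-27b were lower by more than their near-identical paralogs on chromosome 19. If their probes had only measured cross-hybridized miR-23a and miR-27a, the changes would be alike. They differed by −0.37 ± 0.08 for miR-23b against miR-23a and by −0.22 ± 0.04 for miR-27b against miR-27a (SE; exact two-sided permutation p = 0.0079 each, n = 5 per group). This argues against cross-hybridization as the whole cause, and scaling cancels in these differences. Whether the chromosome 9 cluster is transcribed less in Cas/ErbB2 cells was not measured, and the array row stays open.

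Of the 7 miRNAs that fell, 5 were dim, below the median control level of −2.53: miR-149, miR-181a*, miR-378, miR-455-3p and miR-513b. A background error common to all probes would also lower the 2346 probes above background on no array. Their median signal did not fall (a drop of −0.014 ± 0.022, SE, as a share of the smallest drop among the 5). Background had already been subtracted from these signals, which may hold that median level in both groups. The median therefore cannot decide whether background subtraction lowered the 5. Faulty single probes are argued against for miR-149, miR-378 and miR-455-3p, where the other, dimmer probe was lower in Cas/ErbB2 cells for 3 of 3 (exact permutation p = 0.0079, 0.024 and 0.0079, n = 5 per group). These exact tests, like those for miR-222 and miR-23b above, ignored the replicate pairs. The 16 splits that part all numbered pairs are too few for a p under 0.05. Under normexp with its offset of 50, though, all 5 shrank and missed the threshold: miR-455-3p had −0.25 ± 0.11 (adjusted p = 0.34), miR-378 −0.37 ± 0.10 (0.067), miR-513b −0.22 ± 0.11 (0.37), miR-149 −0.18 ± 0.11 (0.41) and miR-181a* −0.23 ± 0.11 (0.34). The same offset on the main signal gave −0.23, −0.34, −0.18, −0.14 and −0.20 in that order. Normexp without it gave −0.72 ± 0.18, −0.71 ± 0.12, −0.57 ± 0.17, −0.50 ± 0.19 and −0.48 ± 0.16. The offset thus accounts for most of the smaller sizes, though miR-455-3p was also smaller without it than in the main fit (−0.93 ± 0.11). Only miR-378 passed without the offset (adjusted p = 0.011), and the other calls depend on the background method.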

How the results depend on the processing

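The fits on slide 1 alone, on slide 2 alone and without both arrays numbered 5, with the normexp offset on the main signal and with normexp without it were added after the data were seen. Main values were 11 miRNAs changed, 0 of them at least 2-fold, and 2 lists. Against these, the 75th percentile over all probes gave 2 miRNAs (1 at least 2-fold) and 2 other lists, the miR-221 cluster and that reported to promote invasion, while both main lists missed (adjusted p = 0.056), no scaling 4 (1 at least 2-fold) and 0 lists, normexp 2 and 1 list, no filter 6 and 6 lists (939 miRNAs tested, most of them at the floor), and array weights 21. Quantile normalization gave 13 miRNAs and 0 lists. Probes above background on all 10 arrays gave the miR-23 clusters in place of the miR-200 family, as did the normexp offset on the main signal, with 3 miRNAs. Probes above background on all 10 arrays left 125 miRNAs, of which 8 changed, all among the 11. miR-149, miR-455-3p and miR-200b were not tested there, as they had entered the main fit only through the group in which they were brighter. Normexp without its offset gave 2 miRNAs and 1 list. The median as scale gave 1 miRNA changed at least 2-fold, a floor set 4 times lower 2, the total gene signal 2 and the authors' values 3. Slide as a block gave 18 miRNAs and 1 list. The replicate block, which pairs the samples, gave 26 miRNAs and 1 list, and of the miRNAs named it changed no call apart from those it added. Slide 1 alone gave 2 miRNAs, 1 at least 2-fold, and 4 lists, slide 2 alone 2 miRNAs, both with fewer arrays. Without both arrays numbered 5 there was 1 list.

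Leaving out each array gave 9 to 16 miRNAs, 0 to 1 at least 2-fold and 0 to 4 lists. The 1 at least 2-fold came without control replicate 4 or Cas/ErbB2 replicate 3. No list passed without Cas/ErbB2 replicate 2 or control replicate 5, 1 passed without control replicate 1 or Cas/ErbB2 replicate 3 or 5, and 4 without Cas/ErbB2 replicate 4. miR-200b changed sign under normexp (−0.036 ± 0.12 SE, log2). With the percentile over all probes, the changes stayed near the main ones while the errors grew. There miR-100 had 0.35 ± 0.26 (SE), against 0.32 ± 0.07 in the main fit, and miR-23b −0.50 ± 0.26, against −0.53 ± 0.10. The misses under that scaling thus reflect a larger error, whose source was not tested. In any other case where no cause is given, none was tested. Of the 11 changed miRNAs, 9 passed in all fits without one array and 0 in all planned settings, 26 at most. Of the 58 others named, 43 passed in none and 15 in at least 1. The detected miRNAs per array differed by −4.3 to 4.7 without one array and by −1.2 and 2.6 under other rules of detection, never past the threshold. Shares of calls that were higher were 36.4% in the main setting, 50.0% with the median or all probes, 46.2% with quantile normalization, 3 of 4 without scaling and 54.5% with the authors' values. Lists were not run on the authors' values, which have empty cells, and array weights did not enter the list test. Signal over background limits miR-149, miR-455-3p, miR-200b and, in Cas/ErbB2 cells, miR-513b (mean −4.77), which lie near the floor.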

Other observations

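The test of hairpin arms was chosen after some values were seen, as were the miRNAs named here. Besides miR-513b, 2 more tested miRNAs of its cluster on chromosome X were lower without passing: miR-509-3p (−0.42 ± 0.15 SE, adjusted p = 0.13) and miR-513a-5p (−0.34 ± 0.13, adjusted p = 0.17). Each was above background on 5 control and 4 Cas/ErbB2 arrays. With the replicate number as a block both passed (limma adjusted p = 0.0060 and 0.038, range over the alternatives up to 0.99). miR-224, also on chromosome X, had −0.36 ± 0.10 (adjusted p = 0.060, and 0.017 with that block). let-7c, clustered with miR-99a on chromosome 21, had −0.08 ± 0.08, against 0.26 ± 0.12 for miR-99a. miR-21, one of the list reported to promote invasion, had 0.00 ± 0.10.

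miR-494 differed most between the slides: it was −1.83 ± 0.22 (log2, SE) on slide 2 against slide 1, with group as a block (limma adjusted p = 0.00090). Its values lay between −3.79 and −1.05 over the 10 arrays, and its SD within groups was 1.07, against a median of 0.20 over the tested miRNAs.

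It was tested whether miRNA genes within 50 kb of each other, as units that may be transcribed together, changed alike. Over 20 pairs among 107 miRNAs with one gene, changes differed by 0.17 on average, against 0.26 for shuffled miRNAs (one-sided permutation p = 0.057 with 100000 shuffles, adjusted p = 0.11 over 2 tests). The rule written before the test counted such a p against a shared change. That rule was wrong, since a p that misses the threshold over 20 pairs does not show that neighbours did not change alike. The reading that neither is decided was set after this p was seen. The pairs span 0.0016 for miR-182 and miR-183 to 1.09 for miR-221 and miR-222. The 7 pairs of arms, matched to a hairpin by name, differed by 0.26 on average, against 0.25 for shuffled miRNAs (one-sided permutation p = 0.56). These few pairs gave no sign of a shared change. One of them is miR-181a* with −0.43, where miR-181a had −0.07. By the probe mappings miR-181a lies on chromosomes 1 and 9 and miR-181a* on chromosome 1 only. The signal of miR-181a can thus also come from another hairpin, and this pair does not compare the arms of a single hairpin.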
